A study of Rattus norvegicus with 18 samples.

How the data were processed

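Per the labels' protocols, RNA of immunopanned astrocytes from postnatal day 5 rat brain was extracted with a column kit, amplified with the SMART-seq HT kit, made into libraries with the Nextera XT kit and sequenced on a NovaSeq6000. Per the submitters' processing notes, HISAT2, StringTie and DESeq2 were used and the genome build was mm10, a mouse build, while per the file headers and values the gene identifiers are rat Ensembl identifiers; the versions of these tools are not given in the sources used here. Which genome the reads were aligned to could not be settled from the table. Per the labels' protocols the doses were 3 ng/ml IFNγ, 1000 U/ml IFNβ, 30 ng/ml TNFα, 3 ng/ml IL1α and 40 ng/ml C1q, whereas the legend in the authors' deposited workbook gives 1000 U/ml IFNγ, 3 ng/ml IFNβ and 400 ng/ml C1q, so the doses are not relied on here.

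The authors' deposited table gives, per the file headers, FPKM for each library, log2 fold changes and adjusted p-values for the 5 comparisons with control. It holds 10434 rows, none with a mean FPKM under 0.501. Left out were 3 rows without a gene name (at most 0.0120% of a library's FPKM). A spreadsheet had turned 17 symbols into numbers, and 15 of them were replaced by the gene symbol found through the Ensembl identifier. Spreadsheet error text in 121 and 120 cells of the authors' deposited IFNγ and IFNβ log2 columns was read as missing. The FPKM of a library summed to 505768 to 542909, the median FPKM was 12.6 to 14.6, and the 10 highest genes took 11.4% to 13.3% of the sum. Median-ratio factors averaged 1.09 in controls, 1.06 with IFNγ, 0.979 with IFNβ, 1.04 with TIC, 0.957 with IFNγ and TIC and 0.925 with IFNβ and TIC. Each library listed 81 to 180 genes at exactly 0, which may stand for a failed estimate, so no fold is given where a whole group was at 0. Whether low values were whole multiples of a read could not be told. Among 1355 genes with a mean FPKM under 2, at most 0.493% shared a ratio between a pair of libraries, against 0.508% after shuffling. Ratios were compared at 4 significant digits. A shared ratio recurs only where many genes hold the same low number of reads, so its absence does not settle the question.

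Genes with 1 FPKM or more in at least 3 libraries (10296) were tested with limma on log2(FPKM + 1), with 1 mean per group, a trend in the prior variance and a single spread estimate over the 18 libraries. The p-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Interactions are the log2 change with interferon on TIC minus the log2 change with interferon alone. Gene lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 210 tests, and again with an estimated correlation. The lists, 19 of genes and 7 of markers of other cells, are: antiviral, guanylate-binding and immunity-related GTPases, IFNγ-linked regulators and chemokines, MHC class I, MHC class II, pan-reactive, A1, A2, NF-κB feedback, cytokines, complement, matrix metalloproteinases, cholesterol synthesis, astrocyte identity, synapse and phagocytosis, cell cycle, endoplasmic reticulum stress, metallothionein and antioxidant, and cell death, with microglia, oligodendrocyte precursors, oligodendrocytes, neurons, endothelial cells, pericytes and ependymal cells. Some genes stand on several lists, so the results of different lists are not independent. The lists, the comparisons, their tests and the settings were chosen before the data were examined. The alternative without jumping genes and some tests of technical explanations, named where they are reported, were chosen afterwards.

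The rule for naming genes, also fixed before the data were examined, took the 8 highest and 8 lowest log2 changes of a comparison among called genes with a log2 change of 1 or more either way, a mean of 5 FPKM or more in a group and no overlap between the libraries of the groups (which 10% of genes would meet by chance), the 4 called list members with the largest change, and a fixed set with Irf1, Gbp2, Ifit3, Cxcl10, B2m, Cd74, C3, Lcn2, Gfap, Vim, Serping1, Nfkbia, Ccl2, Aqp4 and Slc1a2. Not every gene the rule gave is printed, and results for some of the set genes and list members are not reported here. Markers of other cells were named after their values were seen. Overlap expected by chance was computed from the called counts. In 100 simulations of unchanged groups against the same controls, only the shared controls could link the log2 changes. Unchanged groups give almost no calls, so these simulations do not measure how shared controls affect the overlap of calls. Genes were called jumping where a library was at 0.5 FPKM or less and another of its group at 10 FPKM or more. RT1, Ifit, Oas and Gbp genes have near-identical copies, and how the authors' counting split such reads is not given in the sources used here. A genome sequence was not used here. Software was R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.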

Results

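Gene expression was measured by RNA sequencing in 18 libraries of primary immunopanned rat astrocytes from postnatal day 5 brain. Per the labels, cells were kept for 24 h with PBS (control), interferon gamma (IFNγ), interferon beta (IFNβ), a mix of TNFα, IL1α and C1q (TIC), IFNγ with TIC, or IFNβ with TIC, and each of these 6 groups held 3 libraries (n = 3). The values are FPKM from the authors' deposited table, in which 10296 named genes passed a filter of 1 FPKM in at least 3 libraries. Read counts and sequencing depth were not used here. Log2 changes come from limma on log2(FPKM + 1) and are given with their standard error (SE). Levels are group means ± SD in FPKM, and a gene is said to rise or fall where its adjusted p was under 0.05. For a gene list, a bracket with a pair of values gives the median log2 change of its measured genes and the camera adjusted p. The labels do not say whether the 3 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between these libraries.

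The astrocyte genes Gfap (intermediate filament), Aqp4 (water channel) and Slc1a2 (glutamate transporter) stood at 440.0 ± 34.4, 34.4 ± 2.03 and 26.9 ± 1.498 FPKM in controls. Of markers of other cells, the microglial and macrophage genes Aif1 and Fcer1g had control means of 1.09 ± 1.10 and 1.55 ± 1.47 FPKM, and the myelin gene Mbp 0.893 ± 0.554 FPKM. The oligodendrocyte lineage gene Olig1 reached 789 ± 98.8 FPKM and the synaptic vesicle gene Snap25 33.3 ± 5.41 FPKM. Correlation of log2 values between libraries of a group was 0.982 to 0.991, and between groups 0.849 to 0.975. On principal components, the first (50.2% of variance) placed controls at -56.6 to -49.9 and TIC libraries at 28.4 to 30.2. The second (26.0%) placed IFNβ libraries at 36.5 to 37.1, IFNγ libraries at 5.39 to 5.72 and TIC libraries at -43.3 to -40.7.

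**Figure D1:**
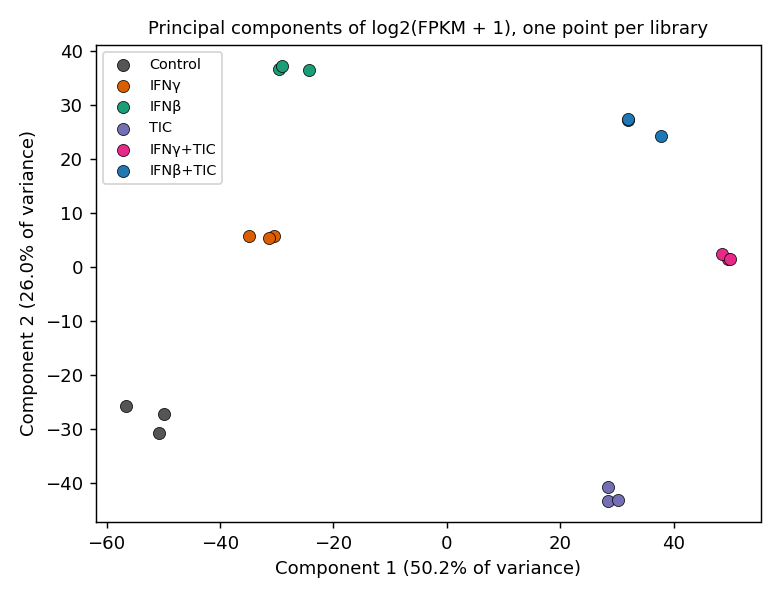
Libraries on principal components 1 and 2 of log2(FPKM + 1), each point 1 library coloured by group, with the share of variance on each axis (50.2% and 26.0%). TIC separates the groups along the first axis, where controls lie at -56.6 to -49.9 and TIC libraries at 28.4 to 30.2, and interferon separates them along the second.

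Among the genes IFNγ raised most were GTPases of cell defence and genes of antigen presentation. Gbp2 (guanylate-binding protein) went from 15.6 ± 2.98 to 1152 ± 11.3 FPKM, a log2 change of 6.14 (SE 0.10). Ifi47 went from 0.855 ± 0.553 to 351 ± 30.3 FPKM (7.61, SE 0.18) and Igtp from 8.13 ± 1.43 to 543 ± 19.1 FPKM (5.91, SE 0.10). Cd74, the invariant chain of MHC class II, was listed at 0 in the 3 control libraries and stood at 163 ± 4.58 FPKM with IFNγ. Ubd, a ubiquitin-like protein, rose by 7.11 (SE 0.22). The transcription factor Irf1 rose by 4.15 (SE 0.15), to 324 ± 14.3 FPKM. Cxcl9, a T cell chemokine at 0.566, 0 and 0 FPKM in controls, reached 72.0 ± 2.67 FPKM (5.97, SE 0.15), and Cxcl10 rose by 4.93 (SE 0.25).

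With IFNγ, 1470 genes were called, 732 higher and 738 lower, of which 253 and 37 moved by a log2 change of 1 or more. After median-ratio scaling the split was 857 higher and 556 lower, as the median change over all genes moved from -0.05 to -0.01. With only the 2 groups compared it was 489 and 315, and without IFNγ 3 it was 625 and 466, so the even split depends on the setting. The MHC class I list had 29 of 29 measured genes higher (median 3.89, camera adjusted p = 2.5e-85), with RT1-A2 at 5.596 (SE 0.07) and the immunoproteasome subunits Psmb9 and Psmb8 at 5.34 and 4.84. B2m, the light chain of class I, rose by 2.73 (SE 0.10). MHC class II had 10 higher and 1 lower of 11 (median 3.20, adjusted p = 6.6e-25), with RT1-Da at 0, 0.0862 and 0 FPKM in controls and 59.4 ± 3.32 FPKM with IFNγ. In the antiviral list 32 of 36 rose (median 2.34, adjusted p = 2.1e-59), among them Bst2, which tethers virions, by 4.16 (SE 0.17), and Ifit3, which binds viral RNA, by 1.86 (SE 0.40), a value that ranged from 1.17 to 2.37 when 1 library was left out. All 6 guanylate-binding and immunity-related GTPases rose (median 5.18, adjusted p = 6.3e-26), as did 15 of 18 regulators and chemokines linked to IFNγ (median 1.40, adjusted p = 1.3e-20). RT1, Ifit, Oas and Gbp genes have near-identical copies between which reads could be split, so values for single members of these families are uncertain throughout.

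In the complement list, 8 of 9 measured genes rose with IFNγ and 1 fell (median 2.26, adjusted p = 1.5e-19). Among them C2 rose by 5.14 (SE 0.10), C1s by 4.66 (SE 0.08), and the C1 inhibitor Serping1 by 4.22 (SE 0.12), from 14.4 ± 3.51 to 280.2 ± 7.21 FPKM. Of reactive astrocyte lists, A1 (linked to inflammation) had 9 of 10 higher and 1 lower (median 2.38, adjusted p = 1.2e-17). The A1 list shares Gbp2, RT1-A2, Psmb8, C3 and Serping1 with the GTPase, MHC class I and complement lists. Its result is therefore not separate from theirs, here and in the other comparisons. Pan-reactive genes had 8 of 13 higher and 1 lower (0.47, 1.8e-06), and A2 (linked to ischaemia) 1 of 9 higher (0.27, 0.00605). C3 rose by 1.14 (SE 0.17) and Lcn2 by 0.53 (SE 0.14), Vim by 0.78 (SE 0.08). Hspb1, a small heat shock protein, fell by 1.46 on the log2 scale and Gfap gave -0.14 (SE 0.08, adjusted p = 0.296). Cytokines had 14 of 25 higher (median 0.79, adjusted p = 7.1e-15), with Ccl5 at 3.46 and Ccl2 at 1.55. NF-κB feedback genes had 9 of 16 higher (0.47, 3.7e-10) and cell death genes 10 of 17 (0.53, 5.4e-10), with Gsdmd, the pore former of pyroptosis, at 1.21 (SE 0.10).

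Genes of the cell cycle fell with IFNγ in 16 of 27 cases (median -0.56, adjusted p = 1.1e-09), with Birc5 at -0.95 (SE 0.19) and Nusap1 at -0.93 (SE 0.15). Cholesterol synthesis had 8 of 25 lower (median -0.17, adjusted p = 3.5e-04, adjusted p = 0.103 with an estimated correlation), with Lss at -0.38. Igfbp5, which binds insulin-like growth factors, fell by 1.91 on the log2 scale, and the lipase Lpl from 9.50 ± 1.53 to 2.57 ± 0.396 FPKM. Slc1a2 fell from 26.9 ± 1.498 to 17.6 ± 1.10 FPKM (-0.59, SE 0.08). The astrocyte identity list had 2 of 23 higher and 5 lower (median -0.16, adjusted p = 0.146), but was called lower without IFNγ 1 (-0.25, adjusted p = 0.0236). Adjusted over the list alone, the counts differed for IFNγ-linked regulators (16 higher), NF-κB (11 higher), cytokines (15 higher, 1 lower), A2 (3 higher), cholesterol synthesis (10 lower), cell cycle (22 lower) and neurons (2 lower, then 3). Of pericyte and fibroblast markers 1 of 5 was higher, the actin-binding Tagln at 1.08 (SE 0.15), with a list median of 0.67 (adjusted p = 0.00861, adjusted p = 0.145 with an estimated correlation) and no call without control 3 (adjusted p = 0.0582). Bsg, a membrane glycoprotein called lower, was listed at 61.8, 63.2 and 0.179 FPKM in the 3 controls and at 0.128, 0.162 and 0 FPKM with IFNγ. It lost its call with no filter (adjusted p = 0.0503), median-ratio scaling (adjusted p = 0.0581), only the 2 groups compared (adjusted p = 0.145), and without control 1, control 2 or any IFNγ library (adjusted p from 0.0925 to 0.195). Lcn2 was no longer called without control 1 (0.36, adjusted p = 0.0754), without IFNγ 3 (0.50, adjusted p = 0.0548) or with only the 2 groups compared (adjusted p = 0.0751), nor was Ifit3 with only those groups (adjusted p = 0.0853).

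IFNβ raised antiviral genes above all. Ifit3 went from 4.02 ± 3.36 to 2232 ± 199 FPKM (9.09, SE 0.40) and Ifit1 from 1.21 ± 0.821 to 675 ± 3.72 FPKM (8.34, SE 0.20). Isg15, a ubiquitin-like modifier, rose from 10.3 ± 3.01 to 3666 ± 318 FPKM (8.38, SE 0.17). Irf7, the factor that amplifies type I interferon, rose by 8.57 (SE 0.23) to 2336 ± 99.6 FPKM. Usp18, which removes Isg15 and damps the receptor, rose by 7.95 (SE 0.17) and the galectin Lgals9 by 8.49 (SE 0.26). Irf1 reached 116 ± 29.1 FPKM (2.65, SE 0.15) and Cxcl10 4245 ± 589.8 FPKM (7.27, SE 0.25).

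With IFNβ, 3909 genes were called, 912 higher and 2997 lower, 305 and 184 of them by a log2 change of 1 or more. Median-ratio scaling gave 1473 higher and 1641 lower, as the all-gene median change moved from -0.16 to -0.03, so the number of falls depends on the scaling. At a log2 change of 1 or more there were 329 higher and 107 lower with median-ratio scaling, 326 and 339 with rescaling to an equal sum per library (TPM) and 356 and 393 with pseudocount 0.1. All 36 antiviral genes rose (median 5.69, camera adjusted p = 1.6e-86), as did 6 of 6 guanylate-binding and immunity-related GTPases (4.94, 7.6e-21), with Gbp2 at 6.23 (SE 0.10) and Ifi47 at 7.41 (SE 0.18). MHC class I had 29 of 29 higher (4.02, 6.6e-67), with RT1-A2 at 5.55 (SE 0.07) and B2m at 2.62 (SE 0.10). MHC class II had 6 of 11 higher and 1 lower (0.64, 6.1e-06), with the protease Ctss at 4.33 (SE 0.20) and Cd74 at 4.14, 3.09 and 2.85 FPKM. Complement had 7 of 9 higher and 1 lower (3.85, 1.6e-15). Cfb rose from 1.05 ± 0.130 to 254 ± 16.8 FPKM (6.96, SE 0.15), C2 by 4.68, and Serping1 by 2.74 (SE 0.12). Cd59, which blocks the membrane attack complex, fell from 33.7 ± 3.71 to 8.22 ± 0.770 FPKM.

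Regulators and chemokines linked to IFNγ had 9 of 18 higher with IFNβ and 2 lower (median 0.34, adjusted p = 2.6e-07). Cytokines had 11 of 25 higher and 3 lower (0.39, 4.3e-08), with the chemokine Ccl12 at 3.75 (SE 0.29) and the death ligand Tnfsf10 at 3.23. Cell death genes had 8 of 17 higher and 3 lower (0.28, 1.6e-06), with Casp12 at 3.33. A1 genes had 6 of 10 higher and 1 lower (1.78, 2.2e-12) and pan-reactive genes 4 of 13 higher and 3 lower (0.08, 0.0332, adjusted p = 0.168 with an estimated correlation). Of A2 genes 1 of 9 moved each way (0.01, 0.384). Gfap fell from 440.0 ± 34.4 to 142 ± 11.5 FPKM (-1.63, SE 0.08) while Vim rose by 0.56 (SE 0.08). C3 and Lcn2 gave 0.39 (SE 0.17, adjusted p = 0.0766) and 0.22 (SE 0.14, adjusted p = 0.231), with ranges of 0.21 to 0.50 and 0.04 to 0.36 when 1 library was left out. The authors' deposited values have both higher, at 0.80 (authors' adjusted p = 0.0124) and 0.41 (authors' adjusted p = 0.0275). NF-κB feedback genes had 6 of 16 higher and 6 lower (-0.02, 0.0723). Their list was called without control 3 (-0.02, adjusted p = 0.0396) and without IFNβ 2 (0.05, adjusted p = 0.0329).

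Cell cycle genes fell with IFNβ in 25 of 27 cases (median -0.87, adjusted p = 2.9e-08), with Top2a, which untangles DNA, at -1.39 (SE 0.20). Cholesterol synthesis genes fell in 22 of 25 (median -0.48, adjusted p = 3.6e-10), with Lss, which closes the sterol rings, at -1.08 (SE 0.07). Chi3l1, a secreted lectin of reactive glia, fell from 133 ± 19.8 to 36.0 ± 6.31 FPKM, and Mgp, an inhibitor of calcification, from 75.4 ± 4.14 to 10.6 ± 4.40 FPKM. The astrocyte identity list had 1 of 23 higher and 8 lower (-0.26, 0.120), with Sparcl1, which promotes synapses, at -0.89 (SE 0.06). Without IFNβ 1 the list was called lower (-0.29, adjusted p = 0.0493). Counts adjusted over the list alone differed for A1 (8 higher), complement (8 higher), pan-reactive (4 lower), NF-κB (7 lower), cholesterol synthesis (23 lower) and cell death (9 higher, 4 lower). Beside these, Cnp, a myelin and interferon-inducible enzyme, rose by 1.22 (SE 0.09), Tagln by 1.14 (SE 0.15), and Snap25 fell by 1.06 on the log2 scale. Kcnn2, a potassium channel called lower, was listed at 0, 0 and 20.7 FPKM in the IFNβ libraries and 35.5, 40.7 and 31.8 FPKM in controls. After median-ratio scaling Nfkbia (-0.28, SE 0.10) and Slc1a2 (-0.32, SE 0.08) were no longer called, at -0.13 (adjusted p = 0.313) and -0.18 (adjusted p = 0.116). Nfkbia also lost its call with only the 2 groups compared (adjusted p = 0.0797), with library quality weights (0.0502) and without control 2 (0.0894), control 3 (0.0702) or IFNβ 2 (-0.17, 0.172). C3 was called with median-ratio scaling, at 0.46 (adjusted p = 0.0412), with pseudocount 0.1 (0.62, adjusted p = 0.0330) and without IFNβ 1 (0.50, adjusted p = 0.0409), and the pan-reactive list lost its call with median-ratio scaling (adjusted p = 0.124) and without control 1 (0.147) or IFNβ 3 (0.108).

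Set against each other, the interferons differed most in antiviral genes and MHC class II. Each was given at a single dose, on which the sources disagree. An effect of dose therefore cannot be told apart from a difference between the interferons. Ifit3 stood at 2232 FPKM with IFNβ and 14.0 with IFNγ (7.24, SE 0.40). Irf7 stood at 2336 ± 99.6 and 14.7 ± 4.64 FPKM (7.27, SE 0.23), and Cxcl10 was higher with IFNβ by 2.34 (SE 0.25). Cd74 was lower with IFNβ by 5.24 on the log2 scale, and RT1-Da, RT1-Db1 and RT1-Ba by 4.19, 4.04 and 4.03, as was Irf8, a regulator of myeloid and IFNγ genes, by 3.57. Gbp2 and B2m did not differ by call, at 0.09 (SE 0.10, adjusted p = 0.528) and -0.11 (SE 0.10, adjusted p = 0.454). Irf1, Serping1 and Gfap were lower with IFNβ, at -1.497 (SE 0.15), -1.47 (SE 0.12) and -1.49 (SE 0.08), and Cfb higher, at 4.70 (SE 0.15). Mgp, at 363 ± 72.9 FPKM with IFNγ, was lower by 5.01.

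Between IFNβ and IFNγ 2581 genes were called, 594 higher with IFNβ and 1987 lower, 153 and 99 of them by 1 or more on the log2 scale. With median-ratio scaling there were 931 higher and 1073 lower, the all-gene median moving from -0.12 to -0.02, and with pseudocount 0.1 the split at 1 or more was 177 and 222. Antiviral genes were higher with IFNβ in 35 of 36 cases (median 3.43, camera adjusted p = 4.5e-86). MHC class II was lower in 9 of 11 and higher in 1 (-2.89, 8.0e-14). IFNγ-linked regulators were lower in 9 of 18 and higher in 4 (-0.54, 0.0152), and cholesterol synthesis genes lower in 19 of 25 (-0.37, 1.6e-09). NF-κB feedback genes were lower in 12 of 16 (-0.49, 1.4e-04, adjusted p = 0.0659 with an estimated correlation), with Tnfaip2 at -1.57 (SE 0.11). Adjusted over the list alone, counts changed for MHC class II (10 lower), IFNγ-linked regulators (5 higher, 11 lower), A1 (3 lower, then 4), A2 (4, then 5), cell cycle (11, then 13) and pericytes and fibroblasts (2, then 3). The MHC class I list had 4 of 29 higher and 6 lower (-0.04, 0.161), but was called without IFNβ 2 (0.01, adjusted p = 0.0332). Of the genes called in both interferon comparisons with control, 431 were higher in both (64.8 expected), 601 lower in both (214.8 expected) and 34 moved in opposite directions. With median-ratio scaling only 556 genes were lower with IFNγ, so the number of shared falls depends on the scaling. The log2 changes correlated at 0.729, where simulated groups with no effect and the same shared controls gave 0.503 over 100 simulations. The simulations gave 0 shared calls, but groups with no effect give almost no calls at all. That value therefore does not measure what shared controls add to the overlap. The covariance was 0.278 against 0.0145 in the simulations, a difference of 0.263. The 3 control libraries are too few to leave 2 in each part of a split and were not divided, so part of the excess of shared calls may come from the shared controls.

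TIC raised chemokines, an acute phase protein and enzymes of arginine and prostaglandin synthesis. Lcn2, an iron-binding acute phase protein, went from 88.2 ± 19.0 to 2924 ± 203 FPKM (5.06, SE 0.14). The monocyte chemokine Ccl2 rose from 253 ± 33.4 to 10983 ± 1409 FPKM (5.44, SE 0.16) and the neutrophil chemokine Cxcl1 from 41.3 ± 7.44 to 3239 ± 250.1 FPKM (6.27, SE 0.13). Ass1, which makes the arginine precursor, rose from 2.13 ± 0.486 to 526 ± 55.6 FPKM (7.40, SE 0.18) and Ptges, prostaglandin E synthase, by 6.91 (SE 0.19). The growth factor gene Csf2 was listed at 0 in the 3 controls and at 71.8 ± 18.5 FPKM with TIC. Timp4, an inhibitor of matrix proteases, fell from 115 ± 4.57 to 3.86 ± 0.672 FPKM (-4.58, SE 0.12), and Slc6a11, a GABA transporter, by 3.71 on the log2 scale.

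With TIC, 5816 genes were called, 2608 higher and 3208 lower, 664 and 909 of them by a log2 change of 1 or more. After median-ratio scaling the split was 3002 higher and 2882 lower, as the median change of all genes moved from -0.04 to 0.01. NF-κB feedback genes rose in 16 of 16 cases (median 2.28, camera adjusted p = 1.8e-15), with Nfkbia, the inhibitor of NF-κB, at 2.11 (SE 0.10) and Sod2 at 3.15 (SE 0.09). Cytokines rose in 20 of 25 with 1 lower (2.90, 2.1e-14). C3 rose from 1.02 ± 0.141 to 14.7 ± 2.05 FPKM (2.95, SE 0.17), Serping1 by 2.51 (SE 0.12) and Vim by 0.67 (SE 0.08). Gfap fell from 440.0 ± 34.4 to 218 ± 6.66 FPKM (-1.01, SE 0.08). Pan-reactive genes had 12 of 13 higher and 1 lower (1.04, 1.0e-05), with the hyaluronan receptor Cd44 at 2.95 (SE 0.15). A1 genes had 8 of 10 higher and 1 lower (0.96, 1.2e-04) and A2 genes 7 of 9 higher (1.85, 1.0e-05), with Ptgs2, cyclooxygenase-2, at 4.31 (SE 0.23). Complement had 5 of 9 higher and 1 lower (2.37, 0.00251, adjusted p = 0.139 with an estimated correlation).

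Of interferon-linked lists, the antiviral genes had 14 of 36 higher with TIC and 6 lower (median 0.01, adjusted p = 0.195) and the guanylate-binding and immunity-related GTPases 3 of 6 and 1 (0.93, 0.0344, adjusted p = 0.167 with an estimated correlation). The IFNγ-linked regulators had 14 of 18 higher (0.83, 2.0e-06). MHC class I had 23 of 29 higher and 1 lower (1.29, 7.8e-11) and MHC class II 4 and 2 of 11 (0.11, 0.587). Gbp2 rose from 15.6 ± 2.98 to 310.5 ± 17.8 FPKM (4.25, SE 0.10), Irf1 by 1.46 (SE 0.15) and Nos2, inducible nitric oxide synthase, by 5.57 (SE 0.22). Ifit3 gave -0.45 (SE 0.40, adjusted p = 0.363), but was called lower without control 3 (-1.13, adjusted p = 0.00145). Cell cycle genes fell in 26 of 27 cases and rose in 1 (-1.503, 5.0e-10), with Top2a at -2.60 (SE 0.20). The astrocyte identity list had 17 of 23 lower and 4 higher (-1.42, 9.1e-07, adjusted p = 0.0793 with an estimated correlation). The potassium channel Kcnj10 fell (-2.64, SE 0.19), and Aqp4 gave -0.29 (SE 0.13, adjusted p = 0.0730). Cell death genes rose in 12 of 17 and fell in 1 (0.68, 0.00121), and cholesterol synthesis had 10 of 25 higher and 4 lower (0.16, 0.116). The counts adjusted over the list alone moved by 1 for complement (6 higher), astrocyte identity (18 lower) and cholesterol synthesis (5 lower). Markers of other cells moved too: Olig1 and Olig2 fell by 1.92 and 1.61 and Cnp by 1.07, while Flt1, an endothelial receptor, rose by 2.94 (SE 0.13) and Snap25 by 0.64 (SE 0.14). The GTPase list lost its call with a filter at FPKM 5 (adjusted p = 0.0508), with only the 2 groups compared (0.0657) and without control 3 (0.0575). Without control 3 the call was also lost for Cxcl10 (0.69, SE 0.25), which gave 0.34 (adjusted p = 0.204), and 0.43 without TIC 1 (adjusted p = 0.172), and was not called with only the 2 groups (0.112) or with library quality weights (0.0930). B2m (0.30, SE 0.10) gave 0.21 without control 1 (adjusted p = 0.0973) and without TIC 1 (0.101), and was not called with only the 2 groups (0.0562). Slc1a2 (0.21, SE 0.08) lost its call under the replicate block (adjusted p = 0.0504), with rescaling to TPM (0.0980), only the 2 groups (0.0563) and library quality weights (0.0627), and without control 2 (0.108), control 3 (0.0994), TIC 1 (0.125) or TIC 2 (0.0804). Aqp4 was called lower with rescaling to TPM (adjusted p = 0.0353), library quality weights (0.0461) and without TIC 1 (0.0269).

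**Figure D2:**
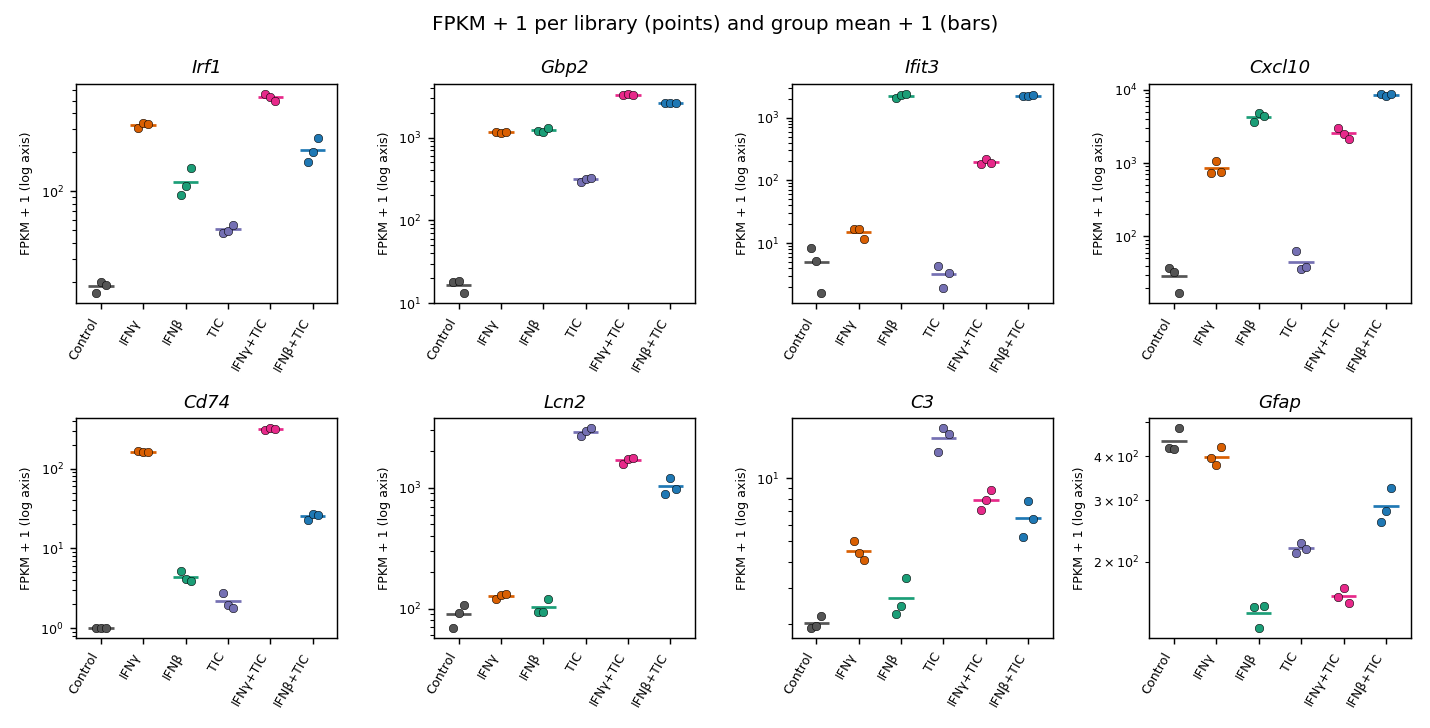
FPKM + 1 on a log axis for Irf1, Gbp2, Ifit3, Cxcl10, Cd74, Lcn2, C3 and Gfap in the 6 groups, each point 1 library and each bar the group mean + 1 (n = 3 per group). Ifit3 stands at 14.0 FPKM with IFNγ and 2232 with IFNβ, and Lcn2 at 2924 FPKM with TIC and 1027 with IFNβ and TIC.

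Added to TIC, IFNγ raised Ubd from 4.795 ± 1.07 to 2998 ± 188 FPKM (9.03, SE 0.22), Ifi47 by 7.84 (SE 0.18), and Cd74 from 1.17 ± 0.527 to 315 ± 8.79 FPKM (7.21, SE 0.14). The chemokines Cxcl9, Cxcl11 and Cxcl10 rose by 7.40 (SE 0.15), 6.04 (SE 0.24) and 5.84 (SE 0.25). Rsad2 (viperin), which blocks viral replication, rose by 6.19 (SE 0.17) and Ifit3 from 2.16 ± 1.21 to 195 ± 19.1 FPKM (6.03, SE 0.40). Lcn2 fell from 2924 ± 203 to 1696 ± 104 FPKM (-0.78, SE 0.14) and C3 from 14.7 ± 2.05 to 6.92 ± 0.853 FPKM (-0.98, SE 0.17). Gchfr, which regulates tetrahydrobiopterin synthesis, fell from 120.6 ± 8.63 to 27.2 ± 0.742 FPKM (-2.11, SE 0.14), P2ry6, a nucleotide receptor, by 2.45 on the log2 scale, and Krt18, a keratin, by 2.19.

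With IFNγ on TIC against TIC, 3006 genes were called, 764 higher and 2242 lower, 265 and 146 of them by 1 or more. Median-ratio scaling gave 1087 higher and 1225 lower (all-gene median -0.12, then -0.02). Antiviral genes rose in 34 of 36 cases (median 3.38, camera adjusted p = 2.4e-71) and the 6 GTPases in 6 (4.29, 3.8e-21). IFNγ-linked regulators rose in 14 of 18 (1.87, 1.0e-21), MHC class I genes in 29 of 29 (3.14, 1.9e-68), and MHC class II in 10 of 11 with 1 lower (3.97, 5.2e-24). Irf1, Gbp2, B2m and Serping1 rose by 3.40 (SE 0.15), 3.41 (SE 0.10), 2.75 (SE 0.10) and 3.01 (SE 0.12). Complement had 7 of 9 higher and 2 lower (2.45, 1.7e-12) and A1 7 of 10 and 2 (2.31, 1.3e-11). Of pan-reactive genes 6 of 13 rose and 2 fell (0.19, 8.3e-04) and of A2 genes 2 of 9 and 4 (-0.48, 0.682). Cytokines had 12 of 25 higher and 5 lower (0.29, 1.1e-04) and cell death genes 9 of 17 and 3 (0.29, 2.9e-08), with Casp1, the inflammasome protease, at 3.30 (SE 0.27). NF-κB feedback genes had 5 of 16 higher (0.20, 2.7e-04, adjusted p = 0.0776 with an estimated correlation). Nfkbia gave 0.15 (SE 0.10, adjusted p = 0.275) and Ccl2 0.21 (SE 0.16, adjusted p = 0.349).

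Cholesterol synthesis fell with IFNγ on TIC in 21 of 25 cases (median -0.38, adjusted p = 2.0e-09), with Hsd17b7 at -1.02 (SE 0.07). Astrocyte identity had 12 of 23 lower and 1 higher (-0.31, 0.00548, adjusted p = 0.316 with an estimated correlation). The gap junction gene Gja1 fell (-0.90, SE 0.06), as did Gfap (-0.46, SE 0.08) and Slc1a2 (-0.37, SE 0.08). Cell cycle genes had 5 of 27 lower (-0.19, 0.463). Adjusted over the list alone, counts changed for IFNγ-linked regulators (15 higher), A2 (5 lower), cytokines (13 higher, 6 lower), cholesterol synthesis (22 lower), cell death (10 higher) and neurons (1 lower, then 2). Beside these, oligodendrocyte precursor markers were lower in 4 of 4 (median -0.91), with Olig1 at -1.11 (SE 0.09), and Tagln rose by 1.73 (SE 0.15). Lmo2, a transcription cofactor called lower, was listed at 33.9, 27.0 and 25.2 FPKM with TIC, at 5.88, 0 and 0 FPKM with IFNγ and TIC, and at 0 in the 3 controls. Vim, at 0.11 (SE 0.08, adjusted p = 0.341), was called after median-ratio scaling (0.23, adjusted p = 0.034).

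Added to TIC, IFNβ raised Ifit3 from 2.16 ± 1.21 to 2227 ± 77.6 FPKM (9.54, SE 0.40) and Ifit1, Ifit2 and Rsad2 by 8.25 (SE 0.20), 8.12 (SE 0.18) and 7.81 (SE 0.17). Cxcl10 went from 44.4 ± 15.0 to 8590.4 ± 412 FPKM (7.61, SE 0.25). Several TIC-raised genes were lower. Mmp9, a matrix protease, went from 60.9 ± 5.73 to 8.35 ± 0.337 FPKM (-2.72, SE 0.10) and Lcn2 from 2924 ± 203 to 1027 ± 162 FPKM (-1.52, SE 0.14). C3 fell from 14.7 ± 2.05 to 5.48 ± 1.30 FPKM (-1.28, SE 0.17) and Ptgs2 fell by 1.93 on the log2 scale. Wnt10a, a secreted Wnt ligand, fell from 24.1 ± 2.72 to 2.04 ± 0.428 FPKM (-3.05, SE 0.14) and Gchfr by 2.74. Gfap and Aqp4 rose, by 0.39 (SE 0.08) and 0.54 (SE 0.13).

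With IFNβ on TIC against TIC, 4263 genes were called, 1015 higher and 3248 lower, 321 and 233 of them by 1 or more. Median-ratio scaling gave 1614 higher and 1693 lower (all-gene median -0.15, then -0.00). Antiviral genes rose in 35 of 36 cases (median 5.82, camera adjusted p = 2.7e-74), the 6 GTPases in 6 (4.0001, 1.2e-16) and MHC class I genes in 29 of 29 (3.20, 9.9e-54). MHC class II rose in 8 of 11 with 1 lower (1.74, 1.4e-10), and IFNγ-linked regulators in 10 of 18 with 1 lower (0.52, 5.5e-09). Irf1, Gbp2, B2m and Cd74 rose by 2.02 (SE 0.15), 3.07 (SE 0.10), 2.64 (SE 0.10) and 3.57 (SE 0.14). Complement had 7 of 9 higher and 2 lower (2.22, 6.5e-11), with Cfb at 5.49 (SE 0.15) and Serping1 at 1.92 (SE 0.12). A1 genes had 7 of 10 higher and 2 lower (1.28, 4.5e-08), pan-reactive 5 of 13 and 2 (0.18, 0.00846, adjusted p = 0.0929 with an estimated correlation) and A2 1 of 9 and 4 (-0.42, 0.709). Cytokines had 9 of 25 higher and 12 lower (-0.07, 0.362), NF-κB feedback genes 3 of 16 and 7 (-0.18, 0.711), with Nfkb1 at -0.80 (SE 0.10) and Sod2 at -0.83 (SE 0.09). Ccl2 and Nfkbia gave 0.01 (SE 0.16, adjusted p = 0.973) and 0.01 (SE 0.10, adjusted p = 0.958). Cell death genes had 8 of 17 higher and 5 lower, with a median of -0.04 but a mean of 0.81 and a camera call toward higher values (2.8e-04), with the caspase Casp12 at 3.09. Zbp1, a nucleic acid sensor, was listed at 0 in the 3 TIC libraries and at 9.42 ± 0.558 FPKM with IFNβ and TIC.

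Cholesterol synthesis fell with IFNβ on TIC in 24 of 25 cases (median -0.69, adjusted p = 1.1e-12), with Hsd17b7 at -1.57 (SE 0.07) and Lss at -1.04 (SE 0.07). Astrocyte identity had 10 of 23 higher and 6 lower (0.24, 0.00670, adjusted p = 0.327 with an estimated correlation). The amino acid transporter Slc7a10 rose (0.89, SE 0.16) and the lipid carrier Apoe fell (-1.14, SE 0.31). Cell cycle genes had 2 of 27 higher and 4 lower (0.18, 0.0488, adjusted p = 0.334 with an estimated correlation). When adjusted over the list alone, counts changed for A2 (2 higher, 5 lower), NF-κB (4 higher), cholesterol synthesis (25 lower), astrocyte identity (11 higher), cell cycle (3 lower), cell death (6 lower) and endothelial cells (1 lower, then 2). The cell cycle list lost its call in 7 other settings (adjusted p from 0.0507 to 0.129). Beside these, Cnp rose by 1.18 (SE 0.09) and Snap25 and Flt1 fell by 1.98 and 1.51. Srm, spermidine synthase, called lower, was listed at 60, 66.1 and 0 FPKM with IFNβ and TIC and 100.3, 101 and 100.3 FPKM with TIC. Srm lost its call with pseudocount 0.1 (adjusted p = 0.0615), median-ratio scaling (0.0650), only the 2 groups compared (0.167), library quality weights (0.0762) and without any one TIC library (0.0736 to 0.0811). Ifnar1, the type I interferon receptor, was listed at 0.558, 32.4 and 25.3 FPKM with TIC and 0.229, 0.471 and 0.397 FPKM with IFNβ and TIC. Ifnar1 lost its call without TIC 2 (-2.23, adjusted p = 0.0842) or TIC 3 (-2.41, adjusted p = 0.0752).

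Against control, IFNγ with TIC gave 6512 called genes (2357 higher, 4155 lower; 3252 and 3202 with median-ratio scaling, all-gene median -0.15, then 0.01) and IFNβ with TIC 6395 (1987 and 4408; 3114 and 3021, median -0.20, then 0.00). Gbp2 reached 3306 ± 85.9 FPKM with IFNγ and TIC (7.66, SE 0.10) and 2620.3 ± 16.6 FPKM with IFNβ and TIC (7.32, SE 0.10). In the same order Serping1 reached 690.0 ± 24.8 and 324 ± 26.9 FPKM, Cxcl10 2539.9 ± 461 and 8590.4 ± 412 FPKM, and Ccl2 12648 ± 164 and 10998 ± 438 FPKM. Lcn2 stayed above control by 4.27 (SE 0.14) and 3.54 (SE 0.14), C3 by 1.96 (SE 0.17) and 1.66 (SE 0.17), and Gfap was below it by 1.47 and 0.62 on the log2 scale. Antiviral genes were higher than control in 34 and 35 of 36 cases (medians 3.58 and 6.02, camera adjusted p = 1.0e-27 and 5.0e-42). NF-κB feedback genes were higher in 16 of 16 in both (2.55 and 2.16; 1.2e-15 and 1.2e-16). MHC class I genes were higher in 29 of 29 in both (3.96 and 4.25; 2.0e-29 and 1.0e-34). Cell cycle genes were lower in 26 of 27 in both (-1.90 and -1.44; 2.1e-08 and 2.7e-07). These counts did not change when adjusted over the list alone. Slc1a2, called lower with IFNβ and TIC (-0.31, SE 0.08), was not called after median-ratio scaling (-0.09, adjusted p = 0.388), where Aqp4 was, at 0.48 (adjusted p = 0.0043).

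Of the markers of other cells on the lists, 5 of 15 for microglia and macrophages, 4 of 8 for oligodendrocyte precursors, 4 of 8 for oligodendrocytes and 4 of 11 for neurons were measured. So were 2 of 9 for endothelial cells, 5 of 10 for pericytes and fibroblasts and 2 of 6 for ependymal cells. The microglia and macrophage list gave medians of 0.39, -0.09 and 0.02 with IFNγ, IFNβ and TIC (camera adjusted p = 0.802, 0.709 and 0.887). Leaving out 1 library moved these medians over 0.12 to 0.79, -0.36 to 0.31 and -0.35 to 0.41. The lysosomal gene Cd68 stood at 42.6 ± 12.5 FPKM in controls and 112 ± 1.60 FPKM with TIC. In the same order the oligodendrocyte precursor list gave -0.03, -0.09 and -0.81, and oligodendrocytes 0.14, 0.03 and -0.29. The neuron list gave -0.48, -1.001 and 0.56 and endothelial cells -0.10, -0.06 and 1.09. Pericytes and fibroblasts gave 0.67, -0.15 and 0.16, and ependymal cells 0.10, -0.24 and 0.89. Olig1 stood at 207 ± 13.1, 95.1 ± 2.55 and 197 ± 22 FPKM in the 3 groups with TIC, and Snap25 at 52.1 ± 4.36, 34.6 ± 4.69 and 12.5 ± 1.58 FPKM. Whether these transcripts came from astrocytes or from other cells was not tested.

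**Figure D3:**
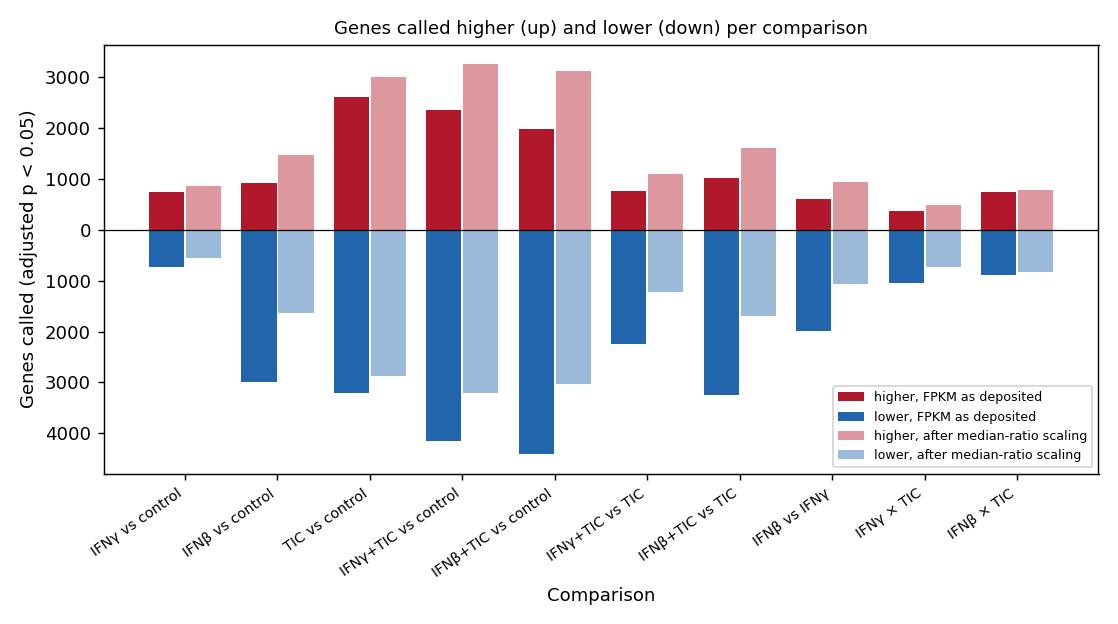
Number of genes called higher and lower at adjusted p under 0.05 in each comparison, of 10296 genes tested. IFNγ against control gave 732 higher and 738 lower and IFNβ against control 912 and 2997.

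**Figure D4:**
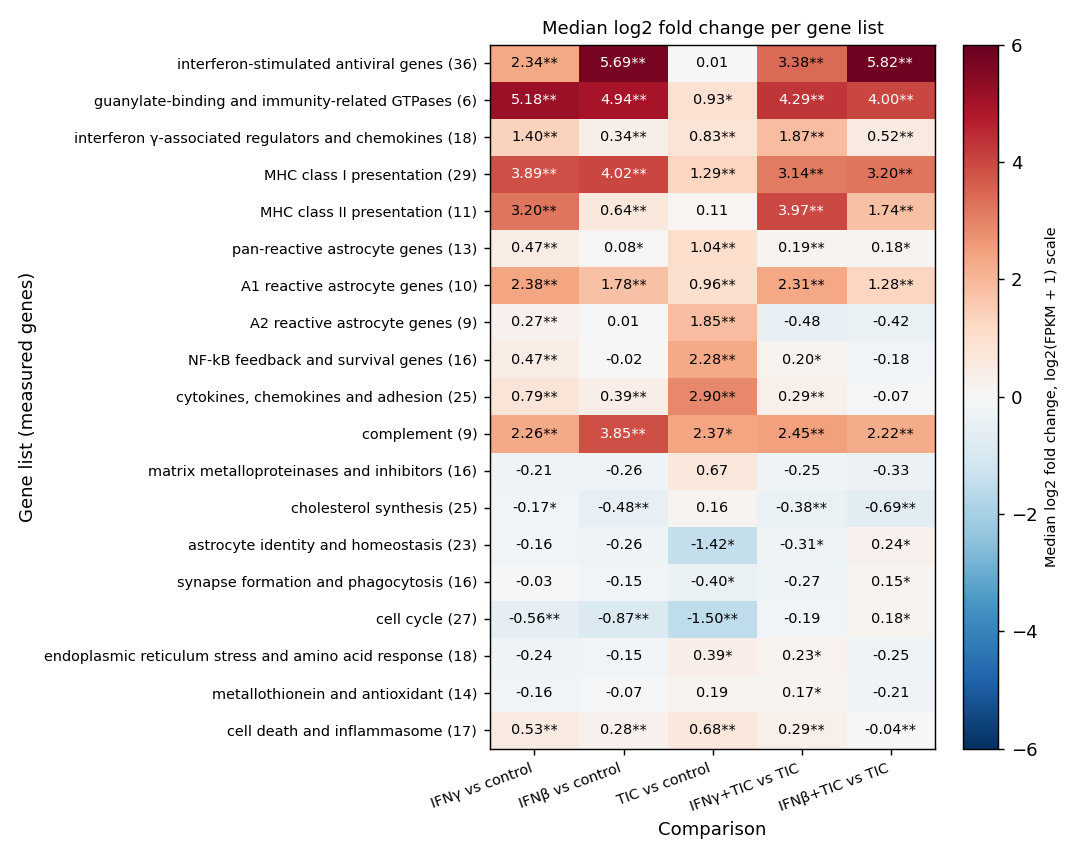
Median log2 change of each gene list in 5 comparisons, with colour and number giving the median, ** a camera adjusted p under 0.05 with the preset and the estimated correlation, and * with the preset only. The antiviral list stands at 2.34 with IFNγ, 5.69 with IFNβ and 0.01 with TIC.

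On the log2 scale, the change with interferon differed in the presence of TIC for 1427 genes with IFNγ (375 with a higher and 1052 with a lower interaction, and 489 and 733 with median-ratio scaling, all-gene median -0.08, then -0.01). For IFNβ this held for 1629 genes (737 and 892; 777 and 824 with median-ratio scaling, 834 and 693 with rescaling to TPM). Ifit3 rose by 1.86 (SE 0.40) with IFNγ alone and by 6.03 (SE 0.40) on TIC, an interaction of 4.17 (SE 0.57), with group means of 14.0 and 195 FPKM. Gbp2 rose by 6.14 (SE 0.10) and 3.41 (SE 0.10), an interaction of -2.73 (SE 0.13), and TIC alone gave 310.5 FPKM. From that higher start, Gbp2 gained more FPKM on TIC than with IFNγ alone, so the sign of its interaction depends on the log2 scale. C3 rose with IFNγ alone (1.14, SE 0.17) and fell on TIC (-0.98, SE 0.17), an interaction of -2.13 (SE 0.23). Gfap fell with IFNβ alone (-1.63, SE 0.08) and rose on TIC (0.39, SE 0.08), an interaction of 2.02 (SE 0.12). B2m gave 0.02 (SE 0.14, adjusted p = 0.955) and 0.02 (SE 0.14, adjusted p = 0.945). Antiviral genes had an IFNγ interaction with a median of 0.71 (camera adjusted p = 1.2e-17). Their IFNβ interaction was not called with both the preset and the estimated correlation. MHC class I genes had an IFNγ interaction of -0.79 (1.7e-12) and, for IFNβ, -0.85 (1.4e-14).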

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

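Of the tests weighed here, the scaling test of the TIC-raised genes was chosen only after their values had been seen; the test on genes chosen in TIC library 1 and the other groupings of the libraries were written down first. The values below, apart from those of the TIC-raised and TIC-lowered genes, were picked out by a test of the difference itself. This test, the interaction term in limma, found that the log2 change with interferon differed with and without TIC. For genes that TIC itself raised, such as Gbp2, a negative interaction need not mean a smaller gain in FPKM. The log2 change differed in this way for 1427 genes with IFNγ and 1629 with IFNβ. With the 4 groups alone, 1341 genes were called for IFNγ and at most 6 in the other groupings drawn. For IFNβ, 1252 genes were called with the 4 groups alone and 1161 in the highest other grouping. Why that grouping called so many was not tested. The other groupings mixed libraries across the 4 groups, so TIC and interferon effects could widen the spread within each mixed group. They therefore cannot decide whether chance gave the interactions.

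With IFNγ, antiviral genes responded more on TIC than alone: Ifit3 (4.17, SE 0.57), Rsad2 (3.34, SE 0.24), Oasl (3.21, SE 0.21), Oas1k (2.49, SE 0.47), Ifit2 (2.47, SE 0.25) and the nuclear body gene Sp100 (2.64, SE 0.28), and their list had a median interaction of 0.71. Rsad2 stood at 64.4 ± 17.5 FPKM with IFNγ and 534 ± 10.1 FPKM with IFNγ and TIC. Regulators and chemokines linked to IFNγ had a median of 0.37, but -0.0338 and no call with pseudocount 0.1 (adjusted p = 0.410). Endoplasmic reticulum stress genes had a median of 0.50 and cell cycle genes of 0.40, and the stress factor Atf3 gave 2.86 (SE 0.41). MHC class I genes (-0.79) and cytokines (-0.49) had negative medians, as had Gbp2 (-2.73, SE 0.13), C3 (-2.13, SE 0.23), Lcn2 (-1.31, SE 0.19), Serping1 (-1.21, SE 0.17), Ccl2 (-1.34, SE 0.22), Irf1 (-0.75, SE 0.21) and Vim (-0.67, SE 0.11). Lower interactions were also found for Ctgf, a matricellular growth factor (-3.36, SE 0.58), the calcium buffer Calb1 (-2.84, SE 0.36), Krt18 (-2.74, SE 0.28), the caveolar coat gene Cav1 (-2.63, SE 0.74) and the fatty acid binding gene Fabp4 (-2.52, SE 0.31), which was listed at 5.69, 4.99 and 5.07 FPKM with TIC and 0, 0.592 and 0.361 FPKM with IFNγ and TIC. Cav1 lost its call with pseudocount 0.1 (adjusted p = 0.0861) and without IFNγ 1 (0.0612), TIC 1 (0.0533) or IFNγ+TIC 2 (0.0645). Irf1 lost its call after median-ratio scaling (adjusted p = 0.0551) and without control 1 (0.0593), IFNγ 3 (0.0504), TIC 3 (0.0620) or IFNγ+TIC 3 (0.0635).

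Among the IFNγ interactions, 3 rest on values that jump between libraries or on groups listed at 0. Marcksl1 (5.07) was listed at 123, 0 and 0 FPKM with IFNγ. It lost its call with pseudocount 0.1 (adjusted p = 0.0574), with only the groups compared (0.0906) and without any 1 library of the 4 groups other than IFNγ 1 (0.0662 to 0.116). Lmo2 (-5.64) was listed at 33.9, 27.0 and 25.2 FPKM with TIC and 5.88, 0 and 0 FPKM with IFNγ and TIC. Ndst2 (-2.85) was listed at 6.06, 5.79 and 6.78 FPKM with IFNγ and at 0 in the control, TIC, and IFNγ with TIC libraries. Where a group was listed at 0, here and for Fabp4 and Cd74 with IFNβ, the value is a difference of log2(FPKM + 1) and not a fold.

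With IFNβ, chemokines and a ubiquitin-like gene rose more on TIC than alone: Ccl4 (3.29, SE 0.53), Ubd (3.09, SE 0.31), Cxcl9 (2.73, SE 0.21) and Cxcl11 (2.58, SE 0.34), as did the vesicle gene Rab3b (2.25, SE 0.18) and Cd74 (1.46, SE 0.19). With pseudocount 0.1, Ccl4 (3.56, adjusted p = 0.111), Cxcl9 (0.73, adjusted p = 0.527) and Cxcl11 (1.73, adjusted p = 0.113) were no longer called, and Cd74 turned to -0.75 (adjusted p = 0.0907). Other positive interactions came from genes that fell with IFNβ alone and not on TIC: Atf3 (2.50, SE 0.41), the lipase inhibitor Angptl4 (2.36, SE 0.22) and Gfap (2.02, SE 0.12), which changed by -1.63 alone and 0.39 on TIC. Aqp4 (0.87, SE 0.19) rose on TIC only. Of lists, cell cycle had a median interaction of 0.90 and MHC class II of 0.80 (0.68 and no call with pseudocount 0.1, adjusted p = 0.0614), against -0.89 for the guanylate-binding and immunity-related GTPases, -0.85 for MHC class I and -0.56 for cytokines. Lower interactions were found for the antiviral membrane gene Ifitm3 (-3.41, SE 0.20), Gbp2 (-3.16, SE 0.13), Gbp4 (-2.52, SE 0.19), Wnt10a (-2.84, SE 0.20), Mmp9 (-2.63, SE 0.15), Ccl7 (-2.35, SE 0.18), Lcn2 (-1.73, SE 0.19), C3 (-1.67, SE 0.23), Ccl2 (-1.58, SE 0.22) and Serping1 (-0.83, SE 0.17). Fabp4 (-2.57) was listed at 0 in the 3 libraries with IFNβ and in the 3 with IFNβ and TIC, Tspan4 (4.03) at 0, 0 and 28.8 FPKM with TIC and 44.1, 28.2 and 56.0 FPKM with IFNβ and TIC, and the ribosomal RNA Rn18s (-2.90) at 129.6, 127 and 159 FPKM with TIC and 31.3, 66.1 and 32.4 FPKM with IFNβ and TIC. Tspan4 lost its call with only the groups compared (adjusted p = 0.0647) and without TIC 1 (0.0621), TIC 2 (0.0681) or IFNβ+TIC 3 (0.0549).

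Alongside the negative values with IFNβ, genes raised at least 2-fold by TIC were lower when IFNβ was added: of 664 such genes, 378 were called lower against TIC and 96 higher, with a median change of -0.52, while IFNγ gave 204 and 129 with a median of -0.14. The intervals given next come from resampling genes and do not measure the spread between libraries. Scaling of the FPKM was weighed first, and after median-ratio scaling the median of 694 TIC-raised genes was still -0.36 (95% interval -0.44 to -0.31), which argues against it. Choosing genes on the same TIC libraries can push the next comparison down, but 724 genes chosen on TIC library 1 had a median of -0.31 (95% interval -0.38 to -0.23) against TIC libraries 2 and 3, which argues against that too. After that scaling IFNγ gave a median of -0.02, while of 822 TIC-lowered genes IFNβ raised 248 and lowered 54 (median 0.19) and IFNγ raised 52 and lowered 196 (median -0.14); as deposited, of 909 such genes these were 189 and 110 (0.08) and 45 and 274 (-0.20). No test of a biological explanation was made, and what lowered these genes is left open.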

How the results depend on the processing

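Counts of called genes stayed within 1.5 times the reported count under pseudocount 0.1, no filter, a filter at FPKM 5 and median-ratio scaling. This also held with rescaling to an equal sum per library (TPM), library quality weights and the replicate block. It held too in 81 cases, each a count taken again without 1 library. Like counts did not mean the same genes. With median-ratio scaling, 2552 of the 3909 genes called for IFNβ against control were still called. The same held for 1988 of 3006 for IFNγ on TIC, 2708 of 4263 for IFNβ on TIC and 5490 of 5816 for TIC against control. With a log2 change of 1 or more required as well, the counts were 290 for IFNγ and 489 for IFNβ against control, 1573 for TIC, 2129 for IFNγ with TIC and 1775 for IFNβ with TIC against control, 411 and 554 for IFNγ and IFNβ on TIC, 252 for IFNβ against IFNγ, and 310 and 382 for the IFNγ and IFNβ interactions; a stricter demand gives fewer genes by construction. With only the groups compared in the fit, IFNγ against control gave 804 genes and the overlap of the interferons 569, with fewer libraries to estimate the spread. Leaving out 1 library gave 1091 to 1351 genes for IFNγ, 3169 to 3598 for IFNβ and 5327 to 5592 for TIC against control.

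With the replicate number as a block the counts were 1475, 3915, 5812, 6512 and 6421 for IFNγ, IFNβ, TIC, IFNγ with TIC and IFNβ with TIC against control, 2997 and 4268 for IFNγ and IFNβ on TIC, 2580 for IFNβ against IFNγ, and 1452 and 1622 for the interactions. The numbers did not pair the libraries: of 45 pairs of libraries with the same number, 6 had residuals correlated above 0.1 (range -0.173 to 0.155), and 7 of 18 libraries were closest to their own number. Leaving out genes whose values jump within a group, an alternative chosen after seeing the data, gave 1491 genes for IFNγ, 3929 for IFNβ and 5824 for TIC against control.

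Of 210 gene list tests, 135 were called with the preset correlation and 94 with an estimated one. Among lists called in the main fit or in the other setting, medians turned direction in few settings, and the cause was not tested. Lists called in neither were not counted, and some of their medians changed sign too, such as microglia and macrophages with IFNβ. The IFNγ-linked regulators had an IFNγ interaction of -0.0338 with pseudocount 0.1 and lost their call (adjusted p = 0.410). The cell death list with IFNβ on TIC had 0.44 with the filter at FPKM 5, 0.12 with median-ratio scaling and -0.0833 to 0.0705 with 1 library left out. With 1 library left out the pan-reactive list ranged from -0.0125 to 0.241 and the NF-κB list from -0.0772 to 0.0530 with IFNβ against control, and MHC class I from -0.0681 to 0.0134 for IFNβ against IFNγ. Of 276 named gene changes, Cd74 turned, with an IFNβ interaction of -0.75 at pseudocount 0.1 (adjusted p = 0.0907). At that pseudocount 10 others lost their call, with median-ratio scaling 11 and with only the groups compared 13. Without 1 library, a call was lost in 86 cases, each a gene change paired with a left-out library. Among those lost at pseudocount 0.1 were the IFNβ interactions of Cxcl9 (0.73, adjusted p = 0.527) and Cxcl11 (1.73, adjusted p = 0.113).

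For 3 libraries against 3 there are only 10 groupings, too few for a share under 0.05. Fitted on the groups compared, the real and the highest other grouping called 804 and 2 genes for IFNγ, 2885 and 3 for IFNβ, 5334 and 1 for TIC, 6415 and 1 for IFNγ with TIC and 5815 and 1 for IFNβ with TIC against control, 3324 and 3 and 3952 and 4 for IFNγ and IFNβ on TIC, and 1794 and 3 for IFNβ against IFNγ. In a self-test on simulated values, 200 genes among 10296 were changed by a set factor, all with 5 FPKM or more in controls. The IFNγ comparison found 79.1% of 1.5-fold and 97.1% of 2-fold changes, with 4.21% of its calls false. The IFNγ interaction found 50.7% and 81.7%, with 6.75% false. Each was a single run with independent normal noise, so recovery of lower or jumping genes was not tested. The authors' adjusted p could be set beside the 5 comparisons with control only. Sequencing depth was not used here, so what it limits was not tested.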

Other observations

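The tests of the jumping values in a single poor library and of the authors' fold changes were chosen only after those values had been seen; the test on neighbouring genes was written down first. Ddit3, a factor of endoplasmic reticulum stress, rose with IFNβ alone (2.37, SE 0.16) and on TIC (2.76, SE 0.16) and with IFNγ on TIC (1.66, SE 0.16), while Atf3 fell with both interferons alone (-1.25 (SE 0.29) and -2.10 (SE 0.29)) and the chaperone Hspa5 rose with TIC (1.11, SE 0.05). The stress and amino acid list had 2 of 18 genes higher and 5 lower with IFNγ (median -0.24, camera adjusted p = 0.151), 4 and 5 with IFNβ (-0.15, 0.298), 11 and 3 with TIC (0.39, 0.0336, adjusted p = 0.281 with an estimated correlation), 7 and 2 with IFNγ on TIC (0.23, 0.00121, adjusted p = 0.103 with an estimated correlation) and 2 and 7 with IFNβ on TIC (-0.25, 0.651). Of metallothionein and antioxidant genes, 3 of 14 were higher and 4 lower with IFNγ (-0.16, 0.497), 3 and 6 with IFNβ (-0.07, 0.831), 7 and 3 with TIC (0.19, 0.202), 3 and 1 with IFNγ on TIC (0.17, 0.00742, adjusted p = 0.328 with an estimated correlation) and 0 and 7 with IFNβ on TIC (-0.21, 0.197), and the cystine transporter Slc7a11 rose with TIC (2.17, SE 0.20) and fell with IFNβ on TIC (-1.76, SE 0.20). Without control 1 the stress list was called lower with IFNγ (-0.37, adjusted p = 0.00766). It lost its TIC call with a filter at FPKM 5 (adjusted p = 0.0564) and without control 1 (0.0867). Adjusted over the list alone, IFNγ lowered 9 stress and 7 antioxidant genes, and on TIC it raised 8 and lowered 4 stress genes, while IFNβ on TIC lowered 8 stress genes.

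Matrix metalloproteinases and inhibitors had 2 of 16 higher and 4 lower with IFNγ (median -0.21, camera adjusted p = 0.315), 1 and 6 with IFNβ (-0.26, 0.502), 9 and 4 with TIC (0.67, 0.0956), 1 and 6 with IFNγ on TIC (-0.25, 0.190) and 2 and 8 with IFNβ on TIC (-0.33, 0.302). Mmp3 and Mmp13, proteases of matrix and collagen, rose with TIC (3.29 (SE 0.46) and 2.87 (SE 0.44)) and fell with IFNβ on TIC (-1.64 (SE 0.46) and -1.37 (SE 0.44)), and the aggrecan protease Adamts1 fell with IFNγ and IFNβ alone (-1.07 (SE 0.23) and -1.09 (SE 0.23)). Synapse and phagocytosis genes had 2 of 16 higher and 4 lower with IFNγ (-0.03, 0.624), 5 and 7 with IFNβ (-0.15, 0.709), 3 and 10 with TIC (-0.40, 0.0196, adjusted p = 0.210 with an estimated correlation), 2 and 8 with IFNγ on TIC (-0.27, 0.127) and 6 and 4 with IFNβ on TIC (0.15, 0.0152, adjusted p = 0.192 with an estimated correlation). The phagocytic receptor Megf10 fell with TIC (-1.34, SE 0.11) and rose with IFNβ on TIC (1.37, SE 0.11), where the receptor Mertk (1.24, SE 0.12) and the synapse-promoting Thbs1 (1.57, SE 0.20) rose too. Adjusted over the list alone, IFNγ raised 3 and lowered 5 genes of each list, and IFNβ on TIC raised 7 synapse genes.

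In 62 genes, among them Bsg, Lmo2, Srm and Marcksl1, a library was listed at 0.5 FPKM or less while another of the same group had 10 FPKM or more, with 19 such genes in the controls, 26 with IFNγ, 20 with IFNβ, 9 with TIC, 13 with IFNγ and TIC and 21 with IFNβ and TIC. A single poor library would hold most of the 140 low values, but the library with most of them, IFNγ 1, held a share of 0.114, which argues against it. Reads given to a neighbouring gene in some libraries would leave that neighbour higher where the gene is low. A neighbour with a log2 rise of 1 or more was found for 1.75% of 57 genes. Chance gave a median of 1.75% and a 95th percentile of 7.02%, so such rises were not in excess. A neighbour already high could gain such reads with a smaller change. The test therefore does not decide whether reads moved to the nearest listed gene on either side. Gene records absent from the authors' deposited table could not be examined. No biological explanation was tested.

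The authors' deposited table also holds log2 changes and adjusted p-values for the 5 comparisons with control. At adjusted p under 0.05 the authors' deposited table called 1361, 2804, 5586, 6490 and 5792 genes for IFNγ, IFNβ, TIC, IFNγ with TIC and IFNβ with TIC, of which 1101, 2051, 5093, 5399 and 4610 were also called by limma on the FPKM, 1101, 2049, 5090, 5396 and 4608 of them with the same sign. The directions in the authors' deposited table were 838 higher and 523 lower, 1585 and 1219, 2890 and 2696, 3348 and 3142, and 3088 and 2704 in that order, where limma on the FPKM gave 732 and 738, 912 and 2997, 2608 and 3208, 2357 and 4155, and 1987 and 4408. FPKM ratios were taken after adding 0.1 FPKM to both group means. In the authors' deposited table Ifit3 had a log2 change of 3.11 with IFNβ where the log2 FPKM ratio was 9.08, Oas1a 1.56 where it was 9.20, and Cxcl9 0.42 with IFNγ where it was 7.96. Calls of single genes differed too. With IFNγ, Ifit3 and Cxcl9 were called by limma but not by the authors' adjusted p (0.215 and 0.0743). With IFNβ, C3 and Lcn2 were called higher by the authors' adjusted p (0.0124 and 0.0275) but not by limma. Of genes with an FPKM change of 4-fold or more, 5 FPKM or more in either group, a control mean above 0 and no jumping values, 30 of 112 with IFNγ and 26 of 165 with IFNβ had less than 0.5 of the FPKM log2 change in the authors' deposited table, against 6 of 464 with TIC, 13 of 707 with IFNγ and TIC and 9 of 533 with IFNβ and TIC. For 51 such genes the columns with TIC held a median ratio of 0.817 (95% interval from resampling genes 0.690 to 0.881). Over all genes of 4-fold or more with and without TIC, the medians with TIC were 1.03 for IFNγ and 1.04 for IFNβ. The shortfall of the 51 genes was thus smaller with TIC but not absent. These values do not decide whether such genes were counted differently for the authors' test. Whether log2 changes were pulled toward 0 in the IFNγ and IFNβ columns of the authors' deposited table stays open: the medians of 0.189 and 0.255 there follow from choosing genes under 0.5, and all genes of 4-fold or more had median ratios of 0.852 with IFNγ, 1.003 with IFNβ, 0.989 with TIC, 0.980 with IFNγ and TIC and 0.968 with IFNβ and TIC. No biological explanation was tested.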
